A study of Paramecium tetraurelia with 12 samples.

How the data were processed

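Total RNA from Paramecium tetraurelia was labelled by reverse transcription and hybridized to an array of clones, 1 dye per sample. Per the labels, images were analysed in GenePix Pro 6.0, and the submitters' processing notes name limma without a version. The spot table holds linear intensity values as deposited by the authors, for 1455 spots at 3 spots per entry. Although it is called raw, its intensities had been background-subtracted (5 lay at or below 0) and shared 1 distribution, with a maximum of 45085.75 in every sample and medians from 201.33 to 204.2. The background method, the spot filters and the array platform are not given in the sources used here. Missing spots ranged from 0 to 537 per sample, and in TV replicate 2 their share lay between 34.4% and 38.7% in each of 4 classes of brightness. Other samples differed. The dimmest class lacked more than the brightest in replicate 1 of TV (13.2% against 6.04%), T0 (7.42% against 3.3%) and T20 (8.79% against 3.3%). In T11 replicate 1 it lacked less (22% against 27.5%). The series matrix, a second deposited table of linear intensity, held 466 features, and 100% of its values equalled the mean of the spots of a clone within 0.01. It was used as an alternative.

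Samples were grouped by their titles. The fit was planned with normexp background correction and an offset of 50 where a table held background separately, which this one did not, so values were used as given. Intensities under 16 (0.611% of the measured spots) were set to 16, a floor chosen after the files were seen. Values were then log2 transformed, quantile normalized between samples and averaged per clone name. limma 3.58.1 in R 4.3.3 fitted all 12 samples with a term for the dye, and lmFit, contrasts.fit and eBayes gave two-sided tests. For each feature the 4 groups shared the same estimate of the spread. Benjamini-Hochberg adjustment ran over the 469 features of each comparison, with a threshold of 0.05. An F test compared the 4 groups. Errors of differences are standard errors and errors of group means are standard deviations. A fold is 2 to the power of the fitted log2 difference. The test was tried on simulated data for T0 against TV with 469 features, where it recovered 52% of 2-fold and 93.2% of 4-fold changes, with 4.41% false calls among all calls. The simulated noise was independent and equally wide in every sample. It held no outlying sample and no deviation shared by samples of the same number, so these shares need not hold for the real data.

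The design, the main test and most alternatives were fixed before the data were examined. Features were to be named where they passed the threshold, changed the same way in 3 same-numbered pairs and were among the 10 largest rises or falls against TV, or the 5 largest in the later steps. Because numbers are not paired with gene names, at most 2 numbered features per direction and comparison are given, with the 3 of T20 against T11 and the 5 clones whose change turned sign. The 42 features named by a word were all tested and counted, a choice made after the files were seen. Single values are given mainly for those that passed a test. N2, N2bis, D7, Spo11 and Orsay07 fall outside the rule because TV replicate 2 lacked a value. The 9 keyword lists fixed in advance needed gene descriptions, which the tables used here do not hold. By name alone the cytoskeleton and cilia list matched 4 features, below the minimum of 5, and the other 8 lists matched 0, so none was tested. The exocytosis, Orsay and VNC119 groups were drawn up after the files were seen, the first after a first look at the fold changes. The RefSeq gene table of assembly ASM14184v1 was not used for names. It has a locus of the same number for 426 of the 428 numbers listed, and its highest locus number, 460, is also the highest listed, but no source used here states that the numbers are locus numbers.

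The series text ties each replicate number to a labelling subset, so the numbers pair the samples. Deviations from the group means correlated at a mean of 0.165 between samples numbered 1 (lowest -0.144), 0.304 between those numbered 2 and 0.506 between those numbered 3. Between different numbers the mean was 0.201 for 1 and 2, where 9 of 12 pairs exceeded 0.1, -0.286 for 1 and 3 and -0.374 for 2 and 3. Deviations within a group sum to 0, so a shift shared by samples numbered 3 would by itself make numbers 1 and 2 alike. The deviations thus set number 3 apart and did not separate numbers 1 and 2, so the pairing rests on the series text. The main fit did not model the pairing, and its dye term joined numbers 1 and 3, both Cy3. The replicate block modelled it as an alternative, and some features passed only with it. Column headings began with an unexplained number, under 400 for replicates 1 and 2 of TV, T0 and T20 and over 700 for all T11 samples and all samples numbered 3. It was treated as a possible batch. Alternatives covered the dye term, the block, the normalization, the filter on dim features, spot averaging, the series matrix, the samples in the fit, the intensity trend, the floor, array weights, the heading number and leaving out samples.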

Results

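Transcript levels were measured in Paramecium tetraurelia, a ciliate that keeps germline and somatic nuclei in one cell, during autogamy, the self-fertilization in which it rebuilds its nuclei. The array carried clones from 1 chromosome and a set of features named by a word. The study's stated purpose was to search that chromosome for genes specific to autogamy. The 12 samples formed 4 groups titled TV, T0, T11 and T20, with 3 samples each. The labels explain neither TV nor the unit of the times. The 3 samples of a group were technical replicates, so p-values measured technical spread only. Each group held 2 samples labelled with Cy3 and 1 labelled with Cy5. Of the 469 features, 42 carried a word as a name and 427 were known by a number only. The files do not pair the numbers with gene names, so such features are given by clone and number.

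Samples of a group correlated at r = 0.882 to 0.969 across features, leaving out pairs with T11 replicate 1. T11 replicate 1 correlated at 0.797 to 0.798 with the other two T11 samples. Features are not independent replicates, so these values describe the samples and are not tests. TV replicate 2 lacked a value for 537 of 1455 spots and T11 replicate 1 for 356. With 3 samples per group, the median standard error was 0.322 on the log2 scale for T0 against TV.

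**Figure D1:**
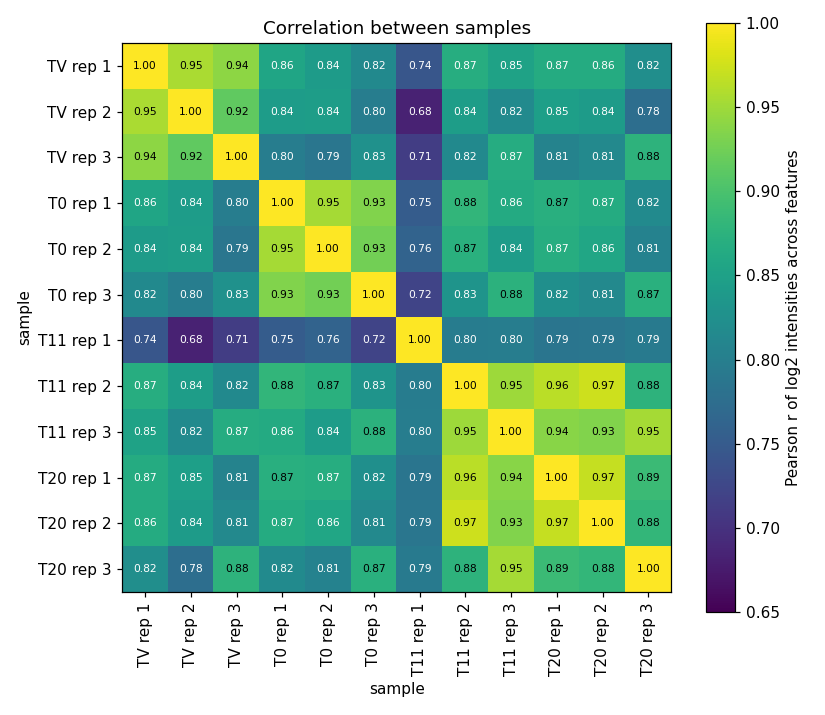
Pearson r of log2 intensity across features for each pair of the 12 samples, with samples on both axes and r as colour and number. T11 replicate 1 reached at most 0.798 with any sample, and T11 and T20 samples without it correlated at 0.876 to 0.974.

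The first comparison, T0 against TV, asked which genes had changed at the first point of the autogamy course. The features named N2 and N2bis showed the largest rises of the 469 tested features. N2 rose 82.1-fold, by 6.36 ± 0.48 on the log2 scale (SE), from a mean of 6.56 ± 0.74 (SD, n = 2) at TV to 13.01 ± 0.24 (SD, n = 3) at T0 (limma adjusted p = 6.54e-06). N2bis rose by 6.13 ± 0.68 (SE, limma adjusted p = 0.00019) from a TV mean of 7.88 ± 1.57 (SD, n = 2), and its rise lay between 5.03 and 7.24 over 27 alternatives. Spo11, the conserved protein that makes the DNA double-strand breaks of meiosis, rose 9.35-fold, by 3.23 ± 0.53 (SE, limma adjusted p = 0.00222). D7 rose by 3.64 ± 0.61 (SE, limma adjusted p = 0.00222) from a TV mean of 5.50 ± 1.11 (SD, n = 2). Values of N2, N2bis, D7 and Spo11 were missing for TV replicate 2, and each was higher at T0 in 2 of 2 same-numbered pairs.

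Spo11 lay at 4.52 ± 0.65 (SD, n = 2) at TV, close to the floor of 16 intensity units set here, and at 7.87 ± 0.54 (SD, n = 3) at T0. Its rise was 3.78 ± 0.64 (SE) with a floor of 1 and 1.88 ± 0.35 (SE) with an offset of 50, so its size depended on the treatment of dim spots. The rise of D7, also dim at TV, was 2.64 ± 0.47 (SE) with the same offset and lay between 2.64 and 4.66 over 28 alternatives. Orsay06 rose by 3.00 ± 0.63 (SE, limma adjusted p = 0.00681), and VNC119AB by 2.15 ± 0.45 (SE, limma adjusted p = 0.00681), both in 3 of 3 pairs. Orsay07 rose by 1.94 ± 0.49 (SE, limma adjusted p = 0.021), in 2 of 2 pairs. Orsay07 lost its call without TV replicate 1 (1.51, limma adjusted p = 0.163) and without T0 replicate 3 (1.54, limma adjusted p = 0.106). No feature named by a word fell, and 35 of the 42 did not pass the test. C56 passed without T0 replicate 1 (1.73, limma adjusted p = 0.0481, against 1.08 and 0.242 with all samples), and DPK8, at 1.06 in both fits, passed without T11 replicate 1 (limma adjusted p = 0.0467, against 0.184). C56 lay close to the floor at TV, at 4.061 and 4.076. Its change with all samples was 1.31 with a floor of 1 and 0.58 with an offset of 50, so its size is uncertain. C12, C34, DPK3, PDEdelta, R1, R2, R3 and TTC8 gave changes from -0.29 to 0.73, and with all samples they and C56 passed in no comparison.

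Of the 6 trichocyst exocytosis genes (ND2, ND6, ND7, ND9, ND169 and NSF), which Paramecium needs to discharge its defensive trichocysts, 0 passed the test in T0 against TV. Their log2 changes lay between -0.33 and 0.43, with a largest SE of 0.63. The 13 Orsay features held the 2 rises given above and 0 falls, and the 5 VNC119 features held 1 rise. The 3 tubulins and centrin, a calcium-binding protein of the cytoskeleton, gave changes between -0.38 and 0.63, and 0 of these 4 passed. Their largest SE was 0.84. The feature alpha1tubuline lay near the top of the shared intensity range, at 15.342 in replicate 3 of both TV and T0, so a rise could hardly show. Among numbered features, clone G4-C10, number 7, rose by 2.48 ± 0.26 (SE, limma adjusted p = 0.000137). Clone I3-G10, number 176, fell by 3.56 ± 0.43 (SE, limma adjusted p = 0.00019), and clone Z4-C11, number 14, fell by 3.52 ± 0.23 (SE, limma adjusted p = 1.05e-06).

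In all, 68 of 469 features changed at T0, 37 higher and 31 lower, and 58 of them by at least 2-fold (limma, adjusted p under 0.05). At most 356 features were measured in all 12 samples, since TV replicate 2 had values for no more. The count was 116 without T11 replicate 1, 45 without T0 replicate 2, 44 over this smaller set of features (18 higher and 26 lower) and 132 with array weights. Within the samples whose column headings began with a low number it was 70, and within those with a high number, 1 sample per group at TV and T0, it was 2.

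**Figure D2:**
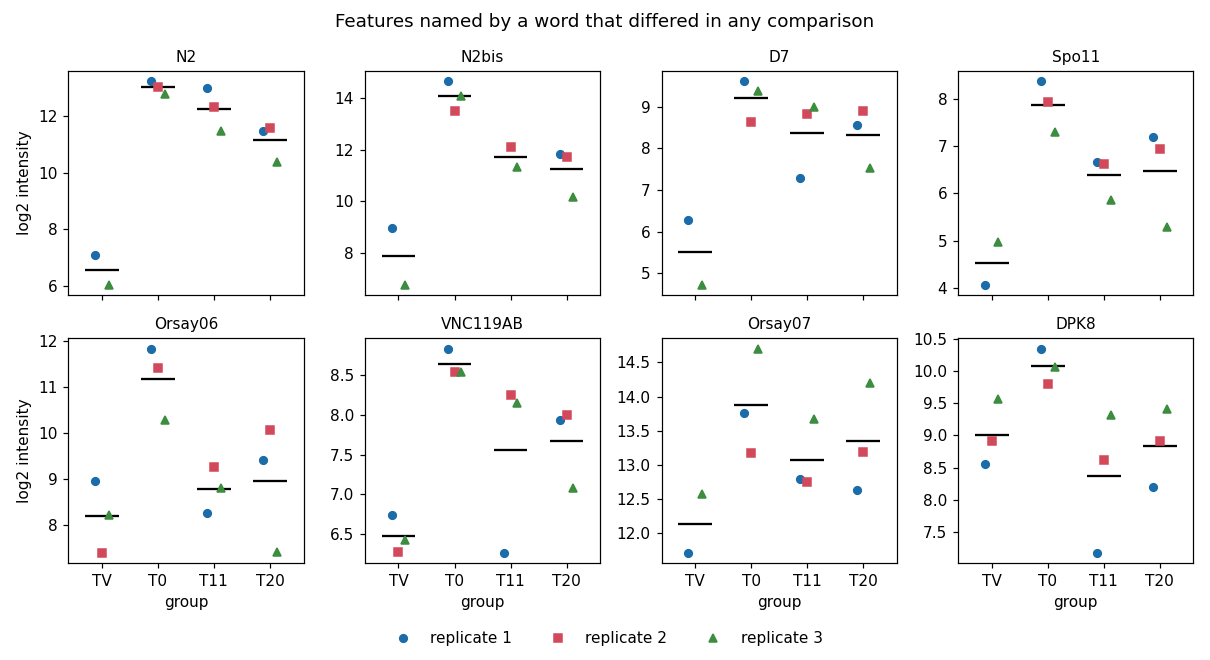
Log2 intensity (vertical axis) of the 8 features named by a word that changed in any comparison, by group (horizontal axis). Points are samples, with symbols for the replicate number, and lines are group means. N2 lay at 6.56 at TV and 13.01 at T0, and Spo11 at 4.52 and 7.87.

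T11 against TV gave the change at the middle time of the course. N2 was 48.9-fold higher than at TV, by 5.61 ± 0.48 (SE, limma adjusted p = 1.8e-05), N2bis was higher by 3.76 ± 0.76 (SE, limma adjusted p = 0.00985) and D7 by 2.79 ± 0.61 (SE, limma adjusted p = 0.0114). Spo11 differed from TV by 1.74 ± 0.53 (SE, limma adjusted p = 0.0576) and did not pass. Clone E2-G5, number 219, rose 18.5-fold, by 4.21 ± 0.28 (SE, limma adjusted p = 1.84e-06), and clone N1-F11, number 444, by 3.12 ± 0.43 (SE, limma adjusted p = 0.000551). Clone N2-F1, number 142, fell by 3.01 ± 0.27 (SE, limma adjusted p = 1.41e-05), and clone Z4-C11 fell by 2.94 ± 0.23 (SE, limma adjusted p = 4.09e-06).

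None of the 6 exocytosis genes passed in T11 against TV, with log2 changes from -0.67 to 0.36, nor did any of the 13 Orsay features, the 5 VNC119 features or the 4 tubulins and centrin. VNC119AB stood at 1.07 ± 0.45 (SE, limma adjusted p = 0.148) and passed without T11 replicate 1, at 1.71 ± 0.30 (SE, limma adjusted p = 0.00318). The calls of D7 (2.01, limma adjusted p = 0.12) and N2bis (2.65, limma adjusted p = 0.0643) ended without TV replicate 3, and that of N2bis also without T11 replicate 2 (3.45, limma adjusted p = 0.0542). Spo11 passed without T20 replicate 3 (1.83, limma adjusted p = 0.0173) with a floor of 1 (2.29, limma adjusted p = 0.0425) and with the replicate block (1.74, limma adjusted p = 0.0234), but stood at 0.79 with an offset of 50 (limma adjusted p = 0.166). It passed in 9 of 26 alternatives, which gave 0.76 to 2.71 and limma adjusted p from 0.0116 to 0.992. With the replicate block Orsay04 (-1.11, limma adjusted p = 0.0239), Orsay07 (1.13, limma adjusted p = 0.0184) and Orsay09 (-1.27, limma adjusted p = 0.0245) also passed.

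In T11 against TV, 56 features changed, 26 higher and 30 lower, 47 of them by at least 2-fold (limma, adjusted p under 0.05). This rests on a spread shared by all groups, although T11 held the outlying replicate 1. With a heading-number term 54 features passed, and 44 of the 56 were among them. All T11 samples had high numbers, so this possible batch was partly confounded with T11. The count fell to 31 without TV replicate 1, 28 without TV replicate 2 and 31 without TV replicate 3. It was 18 with only the groups compared in the fit, 131 with array weights and 3 within the samples with a high heading number, which included all 3 T11 samples.

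T20 against TV gave the change at the last time. N2 was 22.5-fold higher than at TV, by 4.49 ± 0.48 (SE, limma adjusted p = 0.000171), N2bis was higher by 3.31 ± 0.68 (SE, limma adjusted p = 0.00846) and D7 by 2.75 ± 0.61 (SE, limma adjusted p = 0.0107). Spo11 differed by 1.83 ± 0.53 (SE, limma adjusted p = 0.0504), which did not pass. Clone N1-F11 rose by 2.66 ± 0.43 (SE, limma adjusted p = 0.0016) and clone C2-C2, number 369, by 2.45 ± 0.46 (SE, limma adjusted p = 0.00324). Clone E2-C2, number 249, fell by 3.58 ± 0.33 (SE, limma adjusted p = 2.37e-05), and clone D3-B1, number 250, fell by 3.44 ± 0.25 (SE, limma adjusted p = 2.56e-06).

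The exocytosis genes gave 0 calls of 6 in T20 against TV, with changes between -0.20 and 0.38, and the Orsay, VNC119 and tubulin features also gave 0. D7 lost its call without TV replicate 3 (1.96, limma adjusted p = 0.114), without T20 replicate 1 (2.56, limma adjusted p = 0.0504) and without T20 replicate 2 (2.54, limma adjusted p = 0.0572), and N2bis without TV replicate 3 (2.21, limma adjusted p = 0.0867). Spo11 passed without T11 replicate 1 (1.80, limma adjusted p = 0.0396), without T11 replicate 3 (1.87, limma adjusted p = 0.0461), without T20 replicate 3 (2.51, limma adjusted p = 0.0077), with a floor of 1 (2.39, limma adjusted p = 0.0366) and with the replicate block (1.83, limma adjusted p = 0.0171), but stood at 0.90 with an offset of 50 (limma adjusted p = 0.123). In all it passed in 14 of 27 alternatives, which gave 0.32 to 3.19 and limma adjusted p from 0.00139 to 1. VNC119AB, at 1.19 in both fits, passed without T11 replicate 1 (limma adjusted p = 0.00884), and Orsay07 passed without T20 replicate 1 (1.98, limma adjusted p = 0.0204). Orsay07 (1.40, limma adjusted p = 0.005) and Orsay09 (-1.21, limma adjusted p = 0.0126) passed with the replicate block.

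In T20 against TV, 49 features changed, 25 higher and 24 lower, 47 of them by at least 2-fold (limma, adjusted p under 0.05). With the replicate number as a block the count was 82, which included all 49, and without T11 replicate 1 it was 96. It was 110 with array weights, 85 within the samples with a low heading number and 3 within those with a high number, 1 sample per group.

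Features that changed at T11 and T20 overlapped. Of 26 features higher at T11 and 25 higher at T20, 17 were in both sets, against 1.39 for independent lists, and of 30 and 24 lower features 21 were shared, against 1.54. Of 37 features higher at T0, 7 were among those higher at T11, against 2.05, and 8 among those higher at T20, against 1.97. Of 31 features lower at T0, 15 were among those lower at T11, against 1.98, and 17 among those lower at T20, against 1.59. Simulated data without any change, with all 12 samples drawn anew, shared 0 to 0.04 features on average. Few features can pass in such data, so this does not measure what shared TV samples add among called features. The TV samples were not divided, since 1 part would have held a single sample, so part of the excess may come from the shared TV samples.

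T11 against T0 followed the step from the first to the middle time. Clones N2-F8, number 443, and E2-G5 rose by 3.59 ± 0.39 (SE, limma adjusted p = 7.28e-05) and 3.22 ± 0.28 (SE, limma adjusted p = 1.9e-05). Clone Z3-F12, number 353, fell by 3.03 ± 0.26 (SE, limma adjusted p = 1.9e-05), and clone W3-C10, number 186, fell by 2.81 ± 0.29 (SE, limma adjusted p = 4.96e-05). Among features named by a word, Orsay06 fell by 2.40 ± 0.63 (SE, limma adjusted p = 0.0282) and DPK8 fell by 1.70 ± 0.50 (SE, limma adjusted p = 0.0483), each in 3 of 3 pairs. Spo11 differed by -1.49 ± 0.50 (SE, limma adjusted p = 0.0848) and N2bis by -2.38 ± 0.73 (SE, limma adjusted p = 0.0656), and neither passed. None of the 6 exocytosis genes passed.

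The calls of Orsay06 and DPK8 lay near the threshold and were lost without any of several single samples. Without T0 replicate 1, T0 replicate 2, T11 replicate 1, T11 replicate 2 or T11 replicate 3, Orsay06 lay between -1.98 and -2.55, with limma adjusted p from 0.0567 to 0.111. DPK8 lost its call without any 1 of TV replicates 1, 2 and 3, T0 replicates 1, 2 and 3, T11 replicates 1 and 2, and T20 replicate 2, with values from -1.06 to -1.87 and limma adjusted p from 0.0509 to 0.14. Spo11 passed without T20 replicate 3 (limma adjusted p = 0.0351) and N2bis without TV replicate 1 (limma adjusted p = 0.0337) or TV replicate 3 (limma adjusted p = 0.0372). With the replicate block Spo11 (-1.49, limma adjusted p = 0.036), N2bis (-1.97, limma adjusted p = 0.0256) and Orsay09 (-1.25, limma adjusted p = 0.0286) passed. Over all alternatives Orsay06 passed in 19 of 28, DPK8 in 15 of 28, N2bis in 9 of 26 and Spo11 in 4 of 26.

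In T11 against T0, 53 features changed, 22 higher and 31 lower, 50 of them by at least 2-fold (limma, adjusted p under 0.05). These calls too rest on a spread shared by all groups. Of the 37 features higher at T0 than TV, 20 were lower at T11 than T0, against 2.45 for independent lists. Simulated data without any change gave 0, but few features can pass in such data. Of the 31 features lower at T0 than TV, 1 was among the 22 higher at T11 than T0, against 1.45 for independent lists. Both lists use the T0 samples, so part of the overlap may come from them. Over features measured in all 12 samples, 24 were higher and 17 lower. With a heading-number term 50 features passed, and 38 of the 53 were among them. The count was 33 without T0 replicate 1, 31 without T0 replicate 2 and 31 without T0 replicate 3. It was 23 with only the groups compared, 126 with array weights and 4 within the samples with a high heading number, 1 of them from T0.

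**Figure D3:**
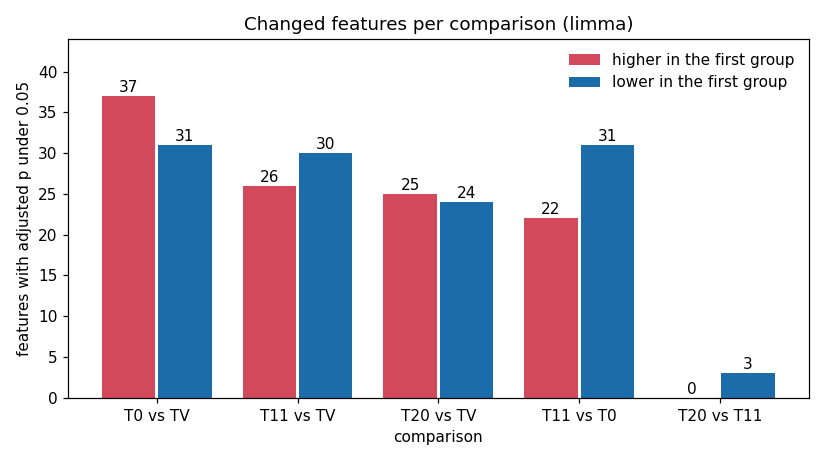
Number of features with a limma adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis), higher or lower in the group named first. T0 against TV gave 37 higher and 31 lower features, and T20 against T11 gave 0 and 3.

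T20 against T11 followed the last step, and 3 clones fell. Clone E2-C2 fell by 2.02 ± 0.33 (SE, limma adjusted p = 0.00834), clone E2-G5 fell by 1.94 ± 0.28 (SE, limma adjusted p = 0.00784) and clone D3-B1 fell by 1.58 ± 0.25 (SE, limma adjusted p = 0.00834), each in 3 of 3 pairs. E2-G5 was still 4.81-fold above TV at T20, by 2.27 ± 0.28 (SE, limma adjusted p = 0.000337). No feature named by a word passed, and N2 stood at -1.12 ± 0.45 (SE, limma adjusted p = 0.975). With limma, 0 features rose, and 22 features had an unadjusted p under 0.05 in either direction. E2-C2 lost its call without T20 replicate 1 (-2.0, limma adjusted p = 0.0534) and D3-B1 without T11 replicate 2 (-1.60, limma adjusted p = 0.0524). The count was 5 without T20 replicate 3, 0 with only the groups compared and 0 within the samples with a high heading number.

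**Figure D4:**
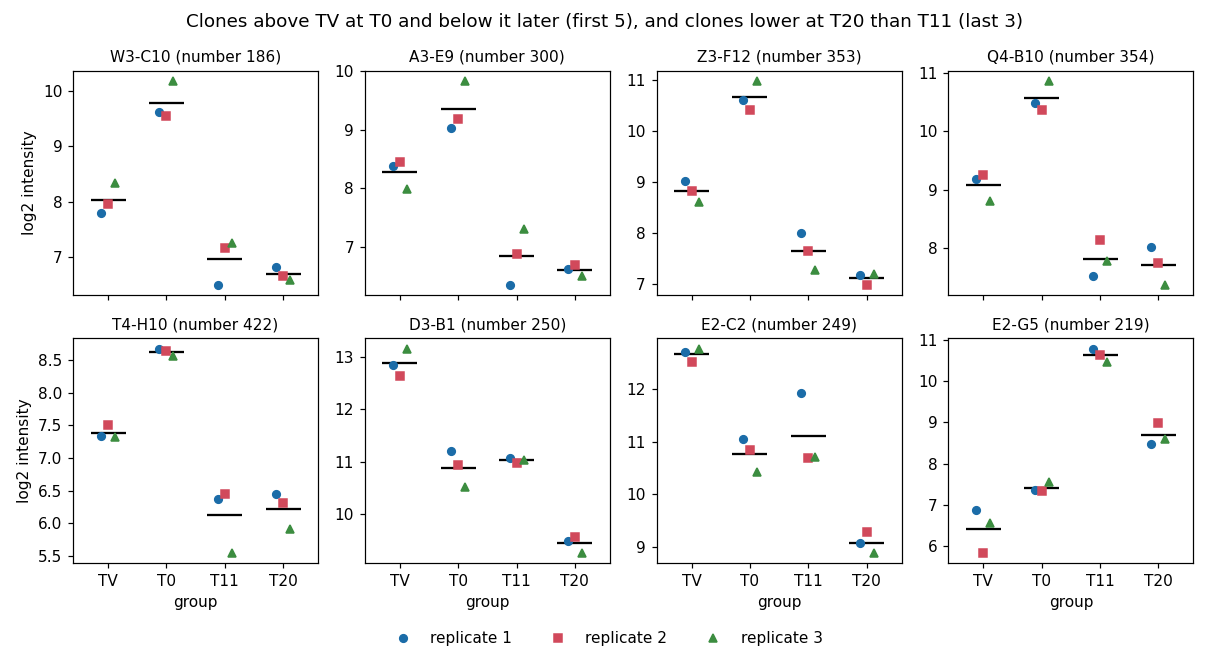
Log2 intensity (vertical axis) by group (horizontal axis) of 5 clones that lay above TV at T0 and below it at T11 and T20, and of the 3 clones lower at T20 than at T11. Points are samples, with symbols for the replicate number, and lines are group means. Clone E2-G5 lay at 10.63 at T11 and 8.69 at T20.

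Over the whole course, N2, N2bis, D7, Spo11, Orsay06, Orsay09 and VNC119AB were the 7 of 42 features named by a word that differed among the 4 groups (limma F test). Orsay09 had limma adjusted p = 0.0462 in this test and passed in no single comparison, with means of 8.44 ± 0.48 (SD, n = 3) at TV and 7.03 ± 0.94 (SD, n = 2) at T11. It passed in T11 against TV without T11 replicate 1 (-1.54, limma adjusted p = 0.0361) or T20 replicate 3 (-1.51, limma adjusted p = 0.0361), and in T11 against T0 without TV replicate 1 (-1.53), T11 replicate 1 (-1.51) or T20 replicate 3 (-1.48). Over all alternatives it passed in 8 of 26 in T11 against TV, 7 of 26 in T11 against T0 and 3 of 27 in T20 against TV. In all, 87 of 469 features (18.6%) passed, and 85 of them had group means at least 1 log2 unit apart. The mean was highest at TV for 26 of these, at T0 for 31, at T11 for 15 and at T20 for 13. Of the 26 highest at TV, 17 were lowest at T0. Of the 31 highest at T0, 9 were lowest at TV, 12 at T11 and 10 at T20. Which mean was highest was not tested. The F test count was 136 without T11 replicate 1, 116 with the replicate block and 197 with array weights.

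No group of features passed camera, limma's test of a set against the other features, over 15 tests of 3 groups. The smallest adjusted p was 0.104, for the 13 Orsay features in T20 against T11, whose median change was 0.33, and the adjusted p was 0.99 with an estimated correlation. The 6 exocytosis genes had an adjusted p of 0.981 in each comparison.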

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

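The tests of a mislabelled sample, of spot quality and of the noise of T11 replicate 1 were chosen only after the results were seen, as were the alternatives with a heading-number term. In 5 clones the level passed as higher than TV at T0 and as lower than TV at T11. They were picked for passing both tests, which largely fixed the difference between T11 and T0, and other features had opposite signs without passing both. The difference was -2.81 for clone W3-C10, -2.50 for A3-E9, -3.03 for Z3-F12, -2.76 for Q4-B10 and -2.50 for T4-H10, with limma adjusted p from 1.9e-05 to 0.000164. All 5 also passed as lower than TV at T20 with all samples, but several calls against TV were lost without 1 sample. At T0, A3-E9 (1.07) lost its call without any 1 of TV replicates 1, 2 and 3, T0 replicates 2 and 3, T11 replicate 2 and T20 replicate 2, with values from 0.81 to 1.20 and limma adjusted p from 0.0528 to 0.153. At T11, W3-C10 (-1.05) lost it without TV replicates 1, 2 or 3, T11 replicates 1 or 2, or T20 replicate 2, with values from -0.79 to -1.21 and limma adjusted p from 0.0522 to 0.13. Also at T11, Z3-F12 and Q4-B10 lost it without TV replicate 1 (-1.09 and -1.19) or TV replicate 2 (-1.11 and -1.20), and A3-E9 without TV replicate 2 (-1.34), with limma adjusted p from 0.0514 to 0.0631. At T20, W3-C10 lost it without TV replicate 3 (-1.18, limma adjusted p = 0.0531), and T4-H10 without TV replicate 2 (-1.18), TV replicate 3 (-1.16) or T20 replicate 2 (-1.13), with limma adjusted p from 0.0528 to 0.0712. The differences between T11 and T0 passed without any single sample.

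T11 replicate 1 stood apart from the other T11 samples, but its mean correlation with them, 0.798, exceeded that with TV by 0.0842 and with T0 by 0.0526. The lower 95% bounds were 0.0428 and 0.0245 over 1000 resamplings of 421 features. This argues against a TV or T0 sample, but the features were taken as independent, so the bounds may be too narrow. The excess over T20 was 0.00885 (-0.00318 to 0.0224), but over the 3 clones called between T20 and T11 without this sample, E2-G5, E2-C2 and D3-B1, it lay at 10.79, 11.92 and 11.06, against at most 8.98, 9.28 and 9.57 in T20 samples. On a scale from 0 at the T20 mean to 1 at the mean of the other T11 samples this was 1.29 (95% interval 0.621 to 1.97, with the clones taken as independent), which argues against a T20 sample. Over 262 clones with all spots measured it correlated with T11 replicate 2 at 0.824, so missing spots alone did not account for it. Poor spot quality stays open, since its median SD between spots of a clone was 0.272 against at most 0.164 on other samples, and no biological explanation was tested, because the 3 samples are technical replicates.

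Few features differed between T20 and T11. Leaving out T11 replicate 1 gave 3 features, as with it, and a heading-number term gave 3 where T11 against T0 gave 50, so neither accounted for the low count. The median SD within T20 and T11 was 1.06 times that within T11 and T0. T11 was in both, which draws this ratio towards 1, and the fit used the same spread for all groups. The ratio therefore does not decide on lower precision. That the samples changed little between these times may be the reason and stays a hypothesis.

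For each pair of groups the 6 samples can be split in 10 ways, too few for a share under 0.05, and the real split was the 1 with the highest count. The real counts were 68 for T0 against TV, 56 for T11 against TV, 49 for T20 against TV, 53 for T11 against T0 and 3 for T20 against T11, and the highest of the other splits was 0 in each. For the F test, 1 of 100 splits of the 12 samples, the real one, gave as many as 87 features. The highest other split gave 16, which argues against chance assignment of these 12 samples to groups as the whole source of that count. The other splits, here and for the pairs of groups, mixed the real groups. Real differences then widen the spread within the split groups, which can lower their counts. The samples are technical replicates and the splits ignored the replicate numbers, so chance differences between cultures were not tested.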

How the results depend on the processing

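The array weights, the floor, the heading number and the filter on complete features were alternatives chosen after seeing the data. Background alternatives could not run, since the spot table has no separate background, and list alternatives were not run because no list was large enough. Over alternatives other than leaving out samples, T0 against TV stayed within 1.5 times its 68 features in 15 of 18, T11 against TV in 14 of 17, T20 against TV in 14 of 18, T11 against T0 in 14 of 17, T20 against T11 in 15 of 17 and the F test in 14 of 15. Some of these alternatives could hardly move a count. The deposited values already shared 1 distribution, which limits what other scaling can change. The series matrix held the same spot means, and the floor touched 0.611% of the measured spots. Asking for at least 2-fold, also among these alternatives, could only lower a count. Array weights gave 132, 131, 110 and 126 features in the first 4 comparisons and 197 in the F test. Samples with high heading numbers gave 2, 3, 3, 4 and 0 in the 5 comparisons, with 1 sample in most groups, and those with low numbers gave 85 for T20 against TV. Complete features, at most 356 of the 469, gave 44 for T0 against TV. With only the groups compared, T11 against TV gave 18, T11 against T0 23 and T20 against T11 0, but T0 against TV gave 92 and T20 against TV 62. Counts with T11 thus fell and those without it rose. The main counts and p-values with T11 rest on T11 varying like the other groups. The replicate block gave 82 for T20 against TV, moved no other count by over 1.5 times and changed no call of a named feature other than those given with their comparisons. The cause was not tested. Leaving out samples gave 21 to 116 for T0 against TV, 12 to 89 for T11 against TV, 14 to 96 for T20 against TV, 17 to 75 for T11 against T0, 0 to 5 for T20 against T11, 32 to 136 for the F test and 32 to 125 for features sorted by highest mean. Where 1 sample of a group was left, it was assumed to vary like the others. Of 2721 values of the 96 called feature changes, 2483 passed, 238 did not and 0 reversed. Many of these changes were picked from the same data as the largest with 3 agreeing same-numbered pairs. A high share that passed and the lack of reversals were thus largely built in. Of 5311 values of 195 uncalled ones, 89 passed. These values left out the fits with only the groups compared, with the intensity trend and with the median of spots. So did the ranges and counts over alternatives given for single features. The fits with only the groups compared cut the T11 counts, as given above, so the share that passed leaves out that loss. Dim features near the floor, such as Spo11 at TV, have uncertain fold sizes.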

Other observations

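The tests of the unnumbered entries and of clones reaching into a neighbouring locus were chosen only after the results were seen. Some clones with consecutive numbers had like courses. Clones E2-C2 and D3-B1, numbers 249 and 250, both fell at T20, with a correlation of 0.99 over the 4 group means. Clones N2-F8 and N1-F11, numbers 443 and 444, both rose at T11, also with a correlation of 0.99. The courses of Z3-F12 and Q4-B10, numbers 353 and 354, were highest at T0 and likewise correlated at 0.99. Both features passed the F test in 20 consecutive pairs, against 13.8 on average for shuffled numbers (permutation p = 0.038, one-sided). Of these 20 pairs, 8 correlated above 0.9, and others ran apart, down to -0.77 for clones r2-F5 and C2-C2 and -0.54 for A3-F6 and F1-H10.

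It was a hypothesis that numbers follow the order along the chromosome and that neighbours change together. Over 395 consecutive pairs the mean correlation was 0.209, above all 10000 shuffles, whose highest was 0.123 (permutation p = 1e-04, one-sided, the smallest they can give). All 15 clones with a second, unnumbered entry sat beside a number missing from the list, against 9.44% of 413 other numbers (Fisher's exact test, p = 4.9e-15, two-sided), so a second entry may stand for a neighbouring gene on the same clone. A clone reaching into the next locus could give part of the likeness. A test of this by the spacing of loci in the RefSeq table, planned before its result was seen, went against it, but is not reported because no source names the genome build of the numbers. The mean correlation was 0.0789 at a distance of 2 numbers (permutation p = 0.0046, one-sided), which would have counted against it, except that 2 clones reaching into the locus between them could also give it. The distance of 3, at 0.0367 (permutation p = 0.12, one-sided), was chosen after that value was seen, so the explanation was neither excluded nor established. Shared regulation of neighbours was not told apart from this.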
